A study of Mus musculus with 14 samples.

How the data were processed

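The data were ChIP-seq peak lists for the transcription factors GATA2 and RUNX1 and for RNA polymerase II phosphorylated at serine 2 (S2P) in mouse G1ER erythroblasts of wild-type (WT) and Chd7 knockout (KO) genotype. The 14 samples comprised 8 immunoprecipitated samples with peak lists and 6 input samples. There were 6 lists, 1 per target and genotype. Each GATA2 and RUNX1 list came from 1 library, whereas each S2P list was named in the labels for both replicates, and how the replicates were combined is not stated. The labels describe chromatin fragments of 500 bp on average, 18 cycles of PCR and selection of amplified fragments of 150 to 300 bp. They name estradiol, for 48 hours, only for a differentiation assay. They do not say which input went with which list, nor whether the cells used for ChIP had been treated with estradiol.

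Reads and peaks were handled with Bowtie2 2.2.1 and MACS2 2.1.0 on the mouse build GRCm38 (mm10), per the submitters' processing notes, which name the tools and builds without their roles or settings. The authors deposited each list in the narrowPeak layout, without a header, so the meaning of each column was checked on its values. The deposited peak score is 10 times the −log10 q cut to a whole number, apart from the rounding of printed values. The deposited fold enrichment is the ratio of the fragment pileup at the summit to the local background estimated by the caller. The deposited −log10 p and −log10 q are the caller's values for each peak, and the lowest −log10 q of each list lay at a q of about 0.05, the limit of the lists. The deposited summit position is an offset in bp from the start of the peak. All peaks lay on the 19 autosomes, X or Y, and no overlapping or adjoining lines were left to merge.

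The pileup at each summit, as a whole number of fragments, and the local background were recovered from the deposited fold enrichment and −log10 p, which together fix both under the caller's Poisson model. In all 6 lists 100% of the summits gave a whole number, with the recomputed −log10 p within 0.005 of the deposited value, and at a wrong scale of 0.93 only 2.83% to 6.57% did. The KO S2P list needed a scale of 0.961 for the ChIP pileup, and 2.81% of its summits were whole without it. Fragment numbers reach a ceiling at 2 times the smallest peak width, between 282 and 298 fragments, so the strongest summits understate differences. Intervals of fragment numbers are exact Poisson 95% intervals. To compare KO with WT summits, fragment numbers were divided by the lowest background of their list, which scales with the depth of the library. Shared summits were compared only where 1 WT peak overlapped 1 KO peak and no other. The background values above the lowest were whole multiples of a fixed step in 55.1% to 67.1% of cases at a tolerance of 0.002, against 1.80% to 7.24% at a step 1.1 times larger, as a control library of whole fragments gives. An earlier check, the share of strong summits at the lowest background, did not show the source and was replaced by this one. The lowest background equalled 1.92 control fragments in both WT factor lists and 1.81 in both KO factor lists, so the GATA2 and RUNX1 lists of a genotype appear to share 1 input, and their backgrounds are not independent.

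Peaks were called shared when they overlapped a peak of the other list by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only: peaks are not replicates, and reads without molecular identifiers are not independent molecules. The overlap given by chance is the mean of 200 circular shifts of the other list within each chromosome. Strength classes are 10 equal parts of a list by −log10 q. Co-occupancy is the share of peaks of a factor overlapped by the other factor in the same genotype.

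Gene positions came from the RefSeq gene table of GRCm38.p6, with 21887 protein-coding genes. The table holds neither strand nor exons, so some planned steps were changed. A peak was assigned to a gene when its summit lay in the gene or within 5 kb of either end, in place of 5 kb upstream. A gene-end peak has its summit within 1 kb of either end, in place of a promoter, and exons and introns were not separated. Motifs at summits were planned and not run, since the genome sequence was not among the reference files. S2P coverage is the percentage of a gene of at least 2 kb lying under S2P peaks, and a gene counted as covered at 50% or more.

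No difference between genotypes was tested, since each target had 1 list per genotype. To describe whether a gene list stood apart, its value was placed among those of 10000 random lists of the same size. Random lists were matched on gene length in 20 classes for binding, and on mean coverage in 10 classes and length in 5 classes for S2P. The resulting percentiles describe these lists and are not p-values. The 10 gene lists were fixed before the data were examined: erythroid, stem and progenitor, megakaryocyte, mast cell, myeloid, lymphoid, non-blood, RUNX and CHD family, housekeeping and cell cycle genes. All listed genes were found in the table except 1 mast cell gene.

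Named genes followed a rule also fixed before the data were examined. It took Chd7, Gata2, Runx1, Gata1 and Cbfb throughout. For each factor it took the 6 genes holding the strongest WT-only, KO-only and shared peaks by −log10 q, among peaks in or within 5 kb of a protein-coding gene. For S2P it took the 8 genes with the largest gain, the 8 with the largest loss and the 4 longest stretches covered in both lists. From each fixed list it took up to 4 members with the strongest peak and up to 4 bound in 1 genotype, and predicted genes were passed over. Further members of the fixed lists are given as examples of S2P coverage, chosen after their values were seen.

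Alternatives comprised a −log10 q of at least 5, a fold enrichment of at least 5, equal numbers of top peaks (as many as 50% of the shorter list), a reciprocal overlap of 50%, and other widths around genes. Leaving out chromosome 5 and some others were added after the data were seen. Fragment recovery, the overlap step and the S2P gene lists were tested on simulated data, and the other steps were not. Fragment numbers were recovered for 100% of 4993 simulated summits at the scale of the factor lists and at that of S2P. None of 25600 simulated intervals was called wrongly in the overlap step. Of 100 unchanged simulated lists of 40 genes drawn from 9000, 5% lay outside the central 95%, and 100% of lists moved by 8 percentage points were found. The real lists had 3 to 46 genes with coverage and median differences of at most 4.08 points. How well differences of that size are found was not tested. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.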

Results

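ChIP-seq profiles of GATA2, RUNX1 and RNA polymerase II phosphorylated at serine 2 (S2P, the form found on elongating polymerase) were collected in G1ER cells. This mouse erythroblast line lacks endogenous GATA1 and carries a GATA1 fusion that estradiol activates. The cells were wild type (WT) or knockout (KO) for Chd7, which encodes a chromatin remodelling ATPase, and the series title names its interaction with RUNX1 in hematopoietic differentiation. Each factor had 1 library per genotype, S2P had 2 replicates per genotype, and each target had 1 peak list per genotype. The lists held 68199 WT and 80611 KO peaks for GATA2, 28952 and 35281 for RUNX1, and 163620 and 165206 for S2P. Median summits rested on 23 and 24 fragments for GATA2, 38 and 37 for RUNX1, and 34 and 35 for S2P, and the lowest local backgrounds were 1.48 and 1.57, 1.37 and 1.39, and 7.00 and 7.07 fragments. With 1 list per target and genotype there was no replicate spread, so every difference below compares the lists and was not tested between genotypes.

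At the targeted gene, Chd7 (chromosome 4, 8690402 to 8868449, GRCm38), neither RUNX1 list had a peak and neither S2P list covered any of the gene. The KO GATA2 list had 1 weak peak there, with 15 fragments (8.40 to 24.7), and the WT list had 0. The locus thus gave no check of the genotype labels. Gata2 held 8 GATA2 peaks in both lists, and 8 WT and 13 KO RUNX1 peaks. Runx1 held 34 WT and 33 KO GATA2 peaks, and 19 WT and 30 KO RUNX1 peaks. Gata1, the master regulator of erythroid maturation, held 5 WT and 7 KO GATA2 peaks and 4 and 5 RUNX1 peaks. Cbfb, which encodes the partner of RUNX1 in DNA binding, held 7 WT and 6 KO GATA2 peaks and 1 and 4 RUNX1 peaks.

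GATA2 occupied every gene of the erythroid list in both genotypes, and its strongest sites were shared. All 56 erythroid genes had a peak in WT and KO, with 437 and 519 peaks in total, and the strongest lay at Alas2, the entry enzyme of heme synthesis, with 249 and 263 summit fragments. Gata1 (241 and 252 fragments at its strongest peak), Zfpm1, the GATA1 cofactor gene (281 in both), and Trim10 (263 in both) followed. Among shared peaks assigned to named protein-coding genes, here and below with predicted genes and sites over 5 kb from a gene passed over, the strongest in WT lay in Kdm6a, a histone demethylase gene (chromosome X, 18179422 to 18179954), with 257 fragments (227 to 290) in WT and 233 (204 to 265) in KO. It was followed by peaks in Tmem33, Marchf1, Cdk14, Prdx3 and Taf3, with 269 to 284 fragments in WT and 274 to 282 in KO, near the ceiling of the measure.

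Peaks called in only 1 genotype included strong sites. Of the WT-only peaks at named genes, the strongest lay in Dop1b (chromosome 16, 93774642 to 93775088), with 179 fragments (154 to 207). It was followed by peaks near Gmfg-ps (88 fragments) and in Adarb2 (96), Plxnc1 (91), Lpcat1 (75) and Dsc3, a desmosomal cadherin gene (55). Of the KO-only peaks at named genes, the strongest lay in Fgf12 (chromosome 16, 28239400 to 28239775), with 134 fragments (112 to 159). Tenm4 (92 fragments), a site within 5 kb of the glutamine synthetase gene Glul (88), Shoc2 (72), Smyd3 (67) and the ectodysplasin receptor gene Eda2r (67) came next. The peaks in Fgf12 and Adarb2 lay in clusters called in 1 genotype alone, given under the other observations, whose cause was not tested.

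Among the other fixed lists, GATA2 was present at 33 WT and 34 KO genes of 43 stem and progenitor genes, led by Erg, Angpt1, Hhex and Runx1. Mecom was bound in KO alone, with only 12 fragments at its strongest peak. GATA2 was present at 17 genes of 20 mast cell genes in each list. Cpa3 (284 and 280 fragments), a mast cell protease gene, Ms4a2, Il1rl1 and Fcer1a were the strongest. Mitf was bound in WT alone (13 fragments) and Fcer1g in KO alone (33). Megakaryocyte genes numbered 19 bound in WT and 17 in KO of 24, with Pf4, Gp9, Nfe2 and Plek the strongest. Gp6 and Mmrn1 were bound in WT alone, each with 14 fragments at its strongest peak. Of 24 housekeeping genes 18 were bound in WT and 22 in KO. Among those bound in KO alone, Npm1, Ldha and Actb had weak peaks of 21 to 28 fragments, and Actb lies on chromosome 5, where KO peaks were more numerous. Of 28 cell cycle genes 23 and 27 were bound, with Cdk2, Pcna, Mcm5 and Cdkn2d in KO alone at 19 to 24 fragments. GATA2 was also present at myeloid genes (15 and 13 of 26; Cebpe, Spi1), lymphoid genes (13 and 12 of 28; Gata3, Rag1) and non-blood genes (13 and 12 of 33; Nphs1, Gfap). The RUNX and CHD family had 13 WT and 14 KO genes bound of 16, the additional member being Chd7. The erythroid count exceeded all 10000 random lists, whose median was 31 genes in WT and 34 in KO. The WT and KO counts also ranked high for the cell cycle (percentiles 99.9 and 100), housekeeping (99.4 and 99.995), mast cell (99.7 and 99.2), stem and progenitor (98.6 and 97.1) and megakaryocyte lists (99.15 and 85.35). They ranked at 87.9 and 46.7 for the myeloid list, 68.8 and 76.3 for the RUNX and CHD family, 19.04 and 3.41 for the lymphoid list and 6.74 and 0.705 for the non-blood list. These random lists were not matched on transcription. Among genes with S2P coverage, 8077 had GATA2 in both lists and 1067 in neither, so a high rank need not be particular to a gene list.

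**Figure D1:**
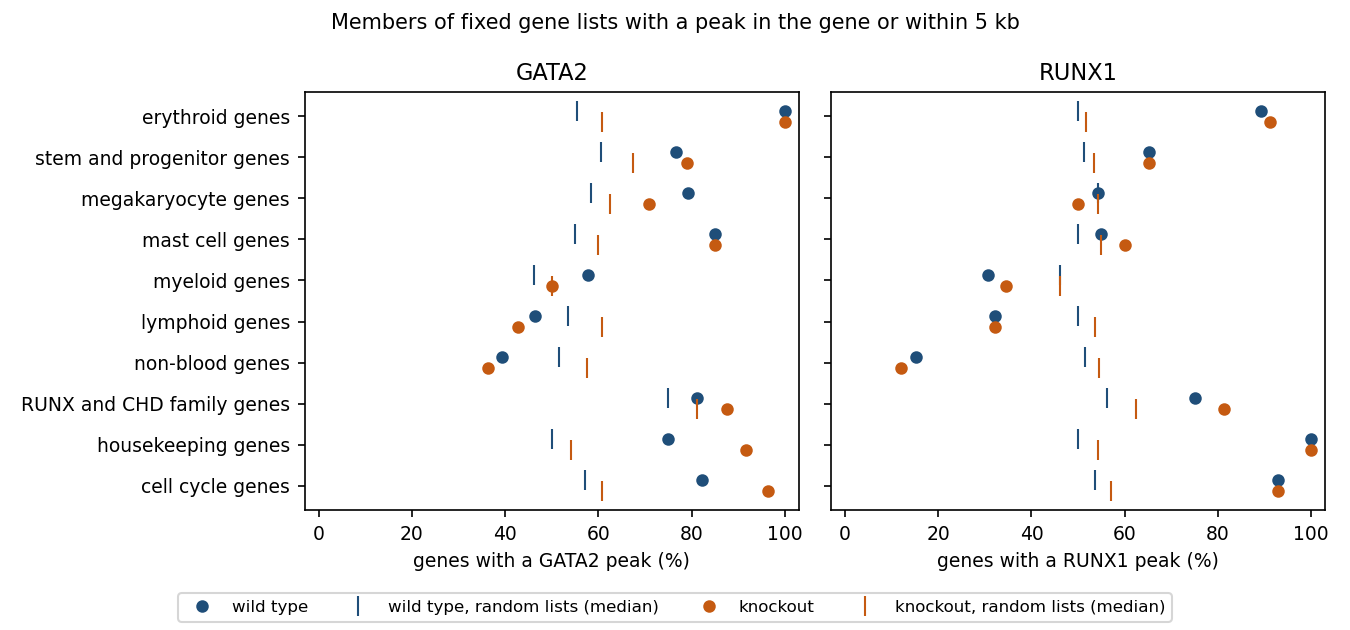
Percentage of the genes of each fixed list with a GATA2 (left) or RUNX1 (right) peak in the gene or within 5 kb, in wild type (blue) and knockout (orange); vertical ticks mark the median of 10000 random lists of matched gene length. All 56 erythroid genes had a GATA2 peak in both genotypes, and all 24 housekeeping genes a RUNX1 peak.

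Of the 21887 protein-coding genes, 11745 had GATA2 in both lists, 634 in WT alone and 1608 in KO alone. KO held 18.2% more GATA2 peaks, and 81.5% of the WT peaks (81.2 to 81.8) and 68.8% of the KO peaks (68.5 to 69.1) were shared, against 1.76% and 1.49% by chance. The KO-only peaks numbered 25163 and the WT-only peaks 12630. Unshared peaks were mostly weak: in the strongest 10% of each list 99.9% of peaks were shared, and in the weakest 10% 51.1% of WT and 30.2% of KO peaks were. Shared summits differed by a median of 0.11 (log2 KO over WT), and by −0.01 in the strongest 10%, where some summits reach the ceiling and differences are understated. Among the top 34099 peaks of each list, which leaves out the weaker peaks of both, 80.3% of WT and 80.03% of KO peaks were shared.

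RUNX1 occupied the housekeeping, cell cycle and erythroid genes most completely, and its list also was longer in KO. All 24 housekeeping genes were bound in both genotypes, with strong peaks at Hsp90ab1, Ppia and Tubb5, and 26 of 28 cell cycle genes, led by Cdk2, Top2a, Cdk6 and Mcm2. Of 56 erythroid genes 50 were bound in WT and 51 in KO, the additional one being the carbonic anhydrase gene Car2 whose strongest KO peak had 21 fragments. The strongest erythroid peaks lay at Zfpm1 (215 fragments in WT and 247 at a different site in KO), Nfe2 (245 and 268), Glrx5 (227 and 266) and Bcl11a, the fetal globin repressor gene (198 and 228). The strongest shared peak at a named gene lay in Banp (chromosome 8, 121955712 to 121956363), with 264 fragments (233 to 298) in WT and 272 (241 to 306) in KO. Rere, Cwc25, Lclat1, Mettl7a1 and the cytochrome P450 reductase gene Por came next, with 238 to 272 fragments in WT.

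Of the WT-only RUNX1 peaks at named genes, the strongest lay in Lca5 (chromosome 9, 83441073 to 83441327), with 95 fragments (76.9 to 116). Plxnc1 (75), Adarb2 (64), Gcnt2 (54), the erythroid tropomodulin gene Tmod1 (70) and Dnah6 (46) followed, and Plxnc1 and Adarb2 also held WT-only GATA2 peaks named above. Of the KO-only peaks at named genes, the strongest lay in Hs2st1 (chromosome 3, 144551379 to 144551813), with 104 fragments (85.0 to 126). Specc1 (67), the mechanosensitive channel gene Piezo2 (69), Eda2r (55), Hacl1 (64) and Inpp4b (72) followed, and the Eda2r site was also a KO-only GATA2 peak.

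In the remaining lists RUNX1 was present at 28 of 43 stem and progenitor genes in each genotype, with Adgrg1, Runx1, Cbfa2t3 and Bcl11a the strongest. It was present at 13 WT and 12 KO megakaryocyte genes (Itgb3, Gp9), 11 and 12 mast cell genes (Gzmb, Cpa3), and 8 and 9 myeloid genes (Cebpe, Cebpb). It was present at 9 lymphoid genes in each list (Ptcra, Vpreb1), 5 and 4 non-blood genes (Pax6, Gfap), and 12 and 13 members of the RUNX and CHD family (Chd9, Cbfa2t2). Members bound in 1 genotype had weak peaks, here with the fragments of the strongest. Those in WT alone were Cd34 (12), Treml1 (20) and Col2a1 (12). Those in KO alone were Bmi1 (20), Hdc (22), Fcgr3 (33) and Chd5 (24). Ranked by bound genes among random lists, RUNX1 lay at percentile 100 for the erythroid, housekeeping and cell cycle lists in both genotypes. The WT and KO ranks were 96.6 and 93.0 for the stem and progenitor list and 91.6 and 95.9 for the RUNX and CHD family. They did not stand out for the mast cell (60.1 and 66.75) and megakaryocyte (57.5 and 29.1) lists. They were low for the myeloid (6.6 and 8.1), lymphoid (2.92 and 1.38) and non-blood (0 and 0) lists. These random lists were matched on length and not on transcription. Among genes with S2P coverage, 8544 had RUNX1 in both lists, 80 in WT alone, 522 in KO alone and 840 in neither. The ranks thus do not separate a preference for a gene list from the wide presence of RUNX1 at genes with S2P coverage. The total number of RUNX1 peaks went from 37 to 36 at megakaryocyte genes and from 24 to 20 at lymphoid genes, ratios of 0.973 and 0.833 at percentiles 2.68 and 0.065 of random lists, whose median ratios were 1.25 and 1.24. The housekeeping (68 to 96) and cell cycle (98 to 141) totals lay at percentiles 79.9 and 88.8, and the other 6 lists between 11.97 and 86.95. The lymphoid total rests on 9 bound genes, against medians of 14 and 15 in its random lists, and counts peaks, not signal. The strongest summits held more fragments in KO at Ptcra (121 and 145), Vpreb1 (75 and 90), Lck (21 and 47) and Cd79a (23 and 56). These are the 4 lymphoid genes with the strongest peaks, and at Lck and Cd79a the site differed.

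RUNX1 was present at 10663 genes in both lists, at 294 in WT alone and at 873 in KO alone. KO held 21.9% more RUNX1 peaks, and 86.6% of the WT peaks (86.2 to 87.0) and 69.6% of the KO peaks (69.1 to 70.1) were shared, against 0.889% and 0.742% by chance. In the strongest 10% 100% of WT and 99.9% of KO peaks were shared, and in the weakest 10% 60.3% and 22.8% were. Shared summits differed by a median of 0.19 (log2 KO over WT), and by 0.14 in the strongest 10%. RUNX1 lay near gene ends more often than GATA2: 29.5% of WT and 30.2% of KO RUNX1 summits were within 1 kb of a gene end, against 6.50% and 6.59% for GATA2. The unshared RUNX1 peaks differed in this, with 10.4% of the 3884 WT-only peaks (9.48 to 11.4) and 25.9% of the 10720 KO-only peaks (25.1 to 26.7) near a gene end. Among the top 14476 peaks of each list 82.7% of WT and 81.8% of KO RUNX1 peaks were shared.

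**Figure D2:**
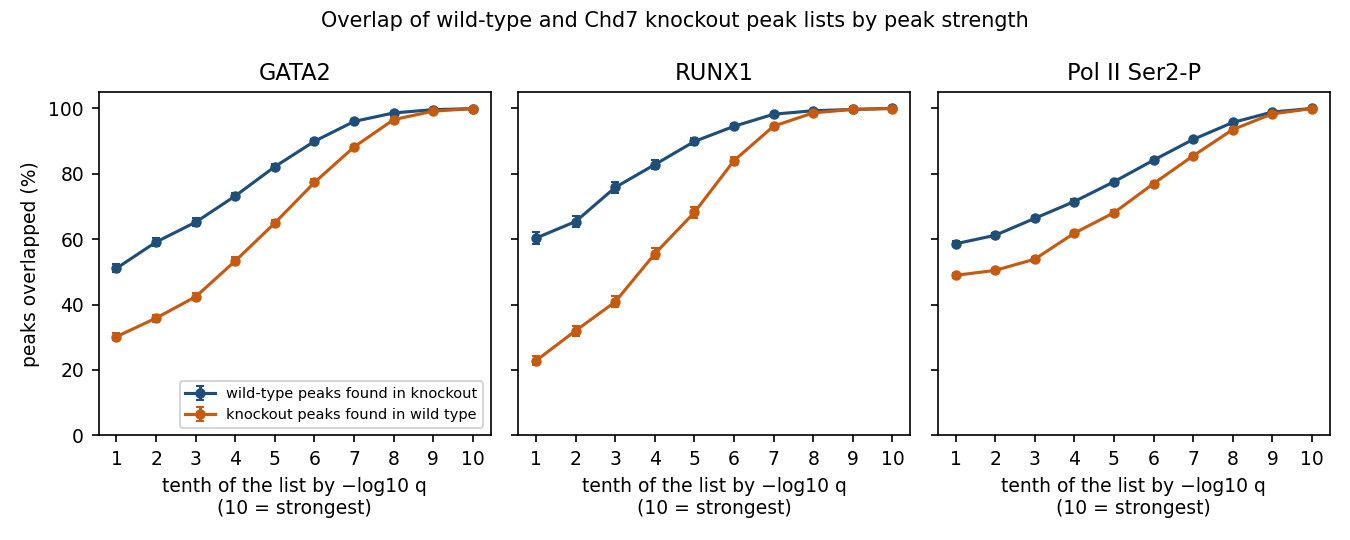
Percentage of peaks overlapped by the list of the other genotype (vertical axis) in each of 10 equal parts of a list by −log10 q, weakest at left, for GATA2, RUNX1 and S2P; bars are exact binomial 95% intervals, which cover counting error only. In the strongest part at least 99.9% of peaks were shared in all 6 lists, and in the weakest part of the KO lists 30.2% (GATA2), 22.8% (RUNX1) and 48.9% (S2P) were.

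Chromosome 5 stood apart in the GATA2 and RUNX1 lists. Shared summits on it differed by 0.46 (GATA2) and 0.56 (RUNX1) in log2 KO over WT, whereas the other 19 chromosomes compared had medians from 0.07 to 0.12 and from 0.13 to 0.19. Peak numbers on it were 1.46 (GATA2) and 1.34 (RUNX1) times higher in KO, against medians of 1.17 and 1.21 elsewhere. In bins of 10 Mb, 16 of 16 (GATA2) and 15 of 16 (RUNX1) bins of chromosome 5 lay above the highest median of any other chromosome. Bins vary more than whole chromosomes, and some bins of chromosomes 4 and 6 lay above that median too. They reached 0.197 for GATA2 and 0.37 for RUNX1, against 0.25 to 0.55 and 0.11 to 0.77 in the bins of chromosome 5. Genes of these comparisons that lie on chromosome 5 include Tmem33, Cdk14, Por, Pf4, Cdk6, Actb, Mettl27 and Fzd9. The Pf4 region, of the megakaryocyte list, had 168 WT and 234 KO fragments at its strongest RUNX1 peak. The S2P lists had no such difference on chromosome 5, where the median was 0.07 against 0.06 to 0.11 elsewhere. Without chromosome 5 KO held 1.17 (GATA2) and 1.21 (RUNX1) times as many peaks as WT.

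**Figure D3:**
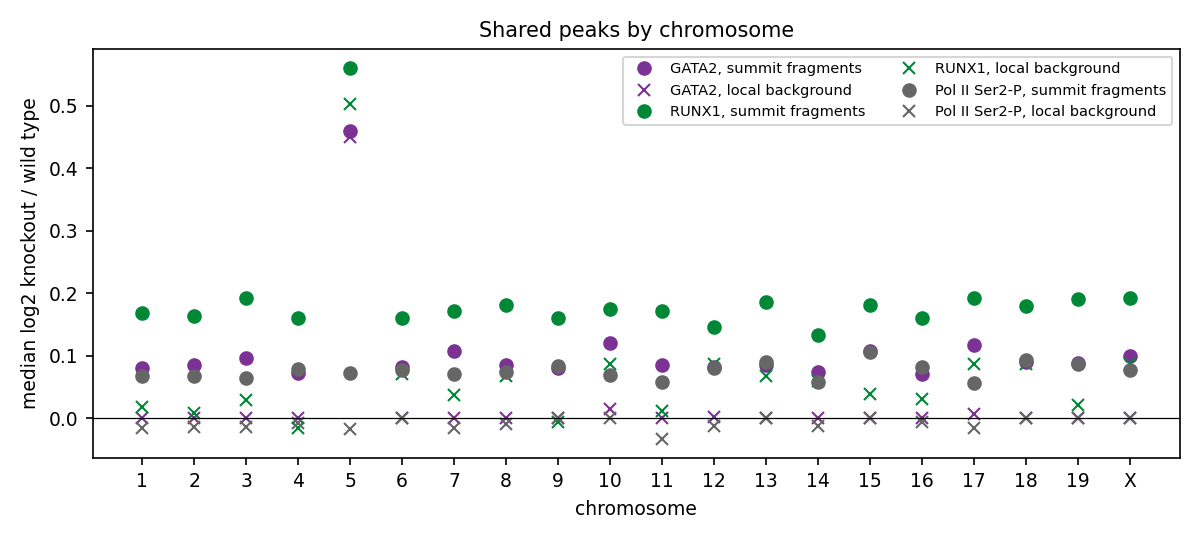
Median log2 ratio of knockout to wild type by chromosome at shared peaks, for summit fragments (circles) and for the local background used by the peak caller (crosses), for GATA2 (purple), RUNX1 (green) and S2P (grey); there is 1 list per genotype, so no error is drawn. Chromosome 5 lies at 0.46 and 0.56 for GATA2 and RUNX1 summits and at 0.07 for S2P.

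GATA2 and RUNX1 shared many sites in both genotypes, and at Gp9, Pf4 and Cebpe the strongest peaks of the 2 factors overlapped in each. At Zfpm1, Runx1, Cpa3 and Nfe2 the strongest WT peaks of the 2 factors lay at separate sites of the same gene. GATA2 overlapped 53.9% of the RUNX1 peaks in WT (53.3 to 54.5) and 52.4% in KO (51.9 to 52.9), against 1.55% and 1.93% by chance. RUNX1 overlapped 22.5% of the GATA2 peaks in each genotype. KO-only RUNX1 peaks were overlapped by KO GATA2 in 42.8% of cases (41.9 to 43.7), and WT-only RUNX1 peaks by WT GATA2 in 55.3% (53.7 to 56.9). Of 10416 sites with RUNX1 in KO alone, 33.3% had GATA2 in both genotypes, 8.10% in KO alone and 57.6% in neither. Sites that were unshared for both factors mostly went the same way: 844 had both in KO alone, such as the site in Eda2r, 337 had both in WT alone, and 109 and 77 went opposite ways. The 2 factor lists of a genotype appear to share 1 input, which can add to such agreement, and on the joint list of sites the odds ratios of 0.710 and 0.241 are no measure of association, since sites without any peak are not in it.

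S2P, which marks gene bodies, covered housekeeping, cell cycle, erythroid and progenitor genes in both genotypes. Covered for at least 50% of their length in both lists were 22 of 24 housekeeping genes, 21 of 28 cell cycle genes, 25 of 48 erythroid genes and 16 of 43 stem and progenitor genes, Lyl1 and Zfp36l2 at 100%. The erythroid genes with coverage were higher in KO in 30 cases and lower in 16. Epb42 (18.0% in WT and 27.6% in KO) and Klf1, an erythroid transcription factor gene (75.2% and 83.3%), were among the higher, and the heme synthesis gene Ppox (37.7% and 27.6%) among the lower. Most genes with S2P coverage were higher in KO, however: 59.0% to 62.5% of them, depending on the class of RUNX1 binding. The KO S2P list also covered more of the genome, 123 Mb against 115 Mb in WT. Of 8 mast cell genes with coverage 7 were lower in KO, among them Cpa3 (54.5% and 39.8%), Cyp11a1 (25.4% and 14.0%) and Il4 (57.7% and 48.1%), and Hpgds was the exception (21.0% and 22.1%). Runx1 was covered for 80.6% in WT and 89.0% in KO, Gata2 for 99.3% and 93.6%, Gata1 for 65.9% and 64.6%, and Cbfb for 35.6% and 40.04%.

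The largest difference in S2P among covered genes was at Glul (chromosome 1, 153899929 to 153909723), covered for 75.5% in WT and 24.1% in KO, beside its KO-only GATA2 peak, and it held 3 WT and 4 KO GATA2 peaks and 2 and 4 RUNX1 peaks. The corepressor gene Ctbp2 (chromosome 7, 132986998 to 133124009) was covered for 53.2% and 14.4%, and it held 6 WT and 3 KO GATA2 peaks and 5 and 1 RUNX1 peaks. Ubqln2, Pet117, Ccdc71l, the Wnt receptor gene Fzd9, Nradd and the histone gene H2bc4 were next, 32.1 to 36.3 points lower in KO. In the other direction, Saysd1 (chromosome 14, 20075636 to 20083172) was covered for 24.997% in WT and 69.7% in KO. Reep2 (36.4% and 67.5%), the proline synthesis gene Pycr1 (23.9% and 53.7%), Pcp2 (64.6% and 93.6%), Egfl8, Zbtb26, Mettl27 and the mitochondrial prolyl-tRNA synthetase gene Pars2 followed. At these genes other than Glul and Ctbp2, the WT and KO counts of peaks of either factor differed by at most 1, and they were equal for both factors at Saysd1, Reep2, Pars2, Pet117, Fzd9, Nradd and H2bc4. The longest stretches covered in both lists lay at Ptpre (61.5 kb), the fatty acid desaturase gene Fads2 (52.0 kb), Cpd (43.4 kb) and the RNA helicase gene Dhx9 (42.0 kb), whose coverage differed by at most 1.73 points.

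**Figure D4:**
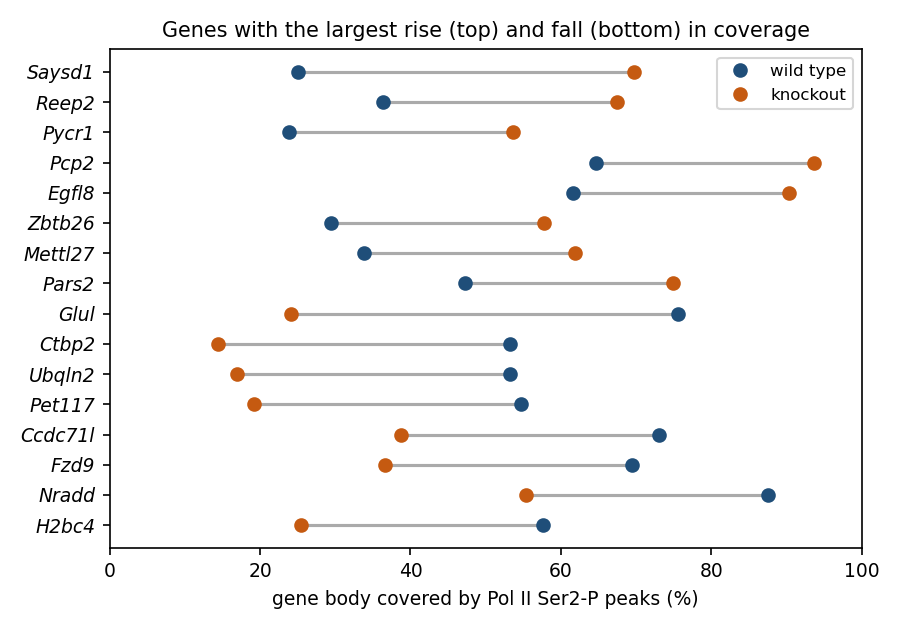
Percentage of the gene body under S2P peaks in wild type (blue) and knockout (orange) for the 8 genes with the largest gain and the 8 with the largest loss among genes covered for at least 50% in a genotype; each point is 1 peak list. Glul went from 75.5% to 24.1% and Saysd1 from 24.997% to 69.7%.

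Of 19304 genes of at least 2 kb, 3225 were covered in WT and 3309 in KO, 3045 of them in both, 180 in WT alone and 264 in KO alone. The median difference among genes covered in either list was 0.136 percentage points (KO minus WT). Of all 19304 genes, covered or not, 57 differed by over 20 points in each direction. S2P lists held 0.969% more peaks in KO, a direction that turned at a −log10 q of at least 5 (ratio 0.994). Of the S2P peaks 80.4% in WT (80.2 to 80.6) and 73.7% in KO (73.5 to 73.9) were shared, against 7.16% and 6.90% by chance, but with a reciprocal overlap of 50% the shares were 44.5% and 44.1%. Set against random lists of matched coverage and length, the median difference of the mast cell list (−2.10 points) lay at percentile 2.02 and that of the erythroid list (1.12 points) at 78.5. The RUNX and CHD family (4.08 points, 9 genes higher and 2 lower) lay at 93.1, the stem and progenitor list (0.454 points) at 41.9, the cell cycle list (0.266) at 69.6 and the housekeeping list (0 points) at 44.6. The megakaryocyte (0.103), myeloid (−0.684), lymphoid (2.88) and non-blood (0.382) lists had 6, 3, 3 and 4 genes with coverage and lay between percentiles 14.3 and 70.7.

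Median differences in S2P were below 1 percentage point both at genes bound by RUNX1 or GATA2 and at genes bound by neither. The 8544 genes with S2P coverage and RUNX1 in both lists had a median difference of 0.802 points (KO minus WT), at percentile 99.99 and above the range of random lists (0.708 to 0.776), although they make up most of the genes drawn from. The 522 genes with RUNX1 in KO alone, among them Car2 (covered for 93.5% in WT and 93.6% in KO) and Bmi1 (25.9% and 18.4%), had 0.320 (percentile 2.71), the 80 with RUNX1 in WT alone 0.602 (82.8), and the 840 with none 0.165 (1.6), below the range of their random lists (0.176 to 0.427). For GATA2 the medians were 0.799 (both, percentile 99.9, above the random 0.705 to 0.777), 0.501 (WT alone, 56.4), 0.317 (KO alone, 24.3) and 0.0415 (neither, 0.335, below the random 0.0902 to 0.504). With RUNX1 summits required within 1 kb of a gene end the medians were 0.879 (both), 0.818 (KO alone), 0.667 (WT alone) and 0.314 (neither), and these were not set against random lists.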

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

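The tests of the background on chromosome 5 at shared summits, of summits over background, of thinning, of peak numbers without chromosome 5 and of the shift of shared summits across chromosomes were chosen only after the result was seen. The test of the background in the KO lists alone was set beforehand.

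The local background estimated by the caller, a signal the peak comparisons do not report on, stood apart on chromosome 5 at shared summits: its KO to WT ratio exceeded the median of the other chromosomes by 0.45 (log2) for GATA2 and 0.46 for RUNX1, beside 0.37 and 0.39 for the summits. Fewer copies in the WT cells were judged on the KO lists alone. Their background on chromosome 5 exceeded the median of their other chromosomes by 0.42 (GATA2) and 0.51 (RUNX1), past the limit set beforehand. In the WT lists the excess was 0.17 and 0. The test cannot exclude this explanation, however, since the background varied widely between chromosomes of 1 list. In KO it was 1.15 (GATA2) and 2.47 (RUNX1) on chromosome 5, and 0.15 to 1.15 and 1.15 to 2.32 on the others. More binding at the same copy number is argued against by the summits over their own background, which on chromosome 5 differed from the rest by −0.0634 (GATA2) and −0.11 (RUNX1). Extra copies of chromosome 5 in the KO cells of these libraries may account for the pattern, as a hypothesis found on the same data: 3 copies against 2 would give 0.58, the backgrounds appear to come from 1 shared input per genotype and count as 1 observation, and the S2P lists had −0.01. An effect of the Chd7 genotype on chromosome 5 was not tested.

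RUNX1 peaks called in KO alone lay near gene ends 15.5 percentage points more often than those called in WT alone, against 1.34 points for GATA2. A difference in peak strength is argued against, since among peaks matched on summit fragments the gap was 12.04 points (10.8 to 13.4, bootstrap 95% interval). The peaks of chromosome 5 are argued against as well, since without them it was 15.4 points. A general gain of RUNX1 signal near gene ends in the KO library may account for it: shared summits there shifted 0.11 (log2) further towards KO than those elsewhere (0.10 to 0.12), just past the 0.1 set beforehand, with the lower bound a little under it. Shared GATA2 summits near gene ends also shifted further, by 0.08, while the GATA2 gap was 1.34 points, so such a shift need not give a large gap. Of all RUNX1 summits 29.5% in WT and 30.2% in KO lay near gene ends, so the whole lists hardly differed. Whether such a gain comes from the genotype or from the library stays open and untested, since each genotype had 1 RUNX1 library.

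The KO lists of GATA2 and RUNX1 held more peaks than the WT lists. Greater depth of the KO libraries is argued against as the whole cause. To come within 5% of the WT number of summits, the KO fragments would need thinning to 85.5% (GATA2) and 83.5% (RUNX1) or less. This held at −log10 p limits of 5 to 30. Matching the WT background takes 94.3% and 98.4%, at least 8.76 percentage points short. This test replaced others that thinned to the background, which hardly moves RUNX1. For GATA2 such thinning lowered the KO to WT ratio from 1.175 to 1.159 at a limit of 5, and from 1.165 to 1.12 at 30. Depth may thus account for part of the GATA2 excess. Chromosome 5 alone is argued against by ratios of 1.17 and 1.21 without it. More efficient immunoprecipitation in KO and higher occupancy cannot be told apart: shared summits shifted towards KO on every other chromosome, by a median of 0.0847 (GATA2) and 0.17 (RUNX1), which either could give with 1 library per genotype. The shift was also larger near gene ends, by 0.08 and 0.11, so it was not even across the genome.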

How the results depend on the processing

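The alternatives without chromosome 5, those of peak numbers, and those that replace strand by both ends of a gene were chosen only after the data were seen. No paired analysis was possible because each target had 1 peak list per genotype and the S2P replicates share a list. Motifs at summits, and settings that need the strand of a gene, were not run.

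Of 95 values of the comparisons under other settings, 48 stayed within their interval or within 1.5 times their count, 46 did not and 1 reversed. The cause was not tested, except that top lists and stricter limits hold fewer peaks and a reciprocal overlap is a stricter demand. The share of WT peaks found in KO exceeded that of KO peaks found in WT for every target in every setting. The longer KO lists of GATA2 and RUNX1 lower the KO share by themselves, so this direction is no separate finding there. A reciprocal overlap pairs the same peaks both ways, so the longer KO list has the lower share for every target. With equal numbers of top peaks the shares were close for GATA2 (80.3% and 80.03%) and RUNX1 (82.7% and 81.8%), but not for S2P (78.4% and 71.6%).

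Shared WT and KO peaks at a −log10 q of at least 5 were 82.3% and 69.3% for GATA2, 72.0% in KO for RUNX1, and 78.0% and 71.7% for S2P. At a fold of at least 5 they were 78.7% and 67.5%, 80.4% and 68.5%, and 79.6% and 62.8%. With equal numbers of top peaks they were 80.3% and 80.03%, 82.7% and 81.8%, and 78.4% and 71.6%. With a reciprocal overlap of 50% they were 75.9% and 64.3%, 76.5% and 62.8%, and 44.5% and 44.1%. Without chromosome 5 the GATA2 shares were 81.1% and 69.4%.

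The KO to WT ratio of peak numbers at a fold of at least 5 was 1.16 for GATA2, 1.16 for RUNX1 and 1.196 for S2P. At a −log10 q of at least 5 it was 1.18 for RUNX1 and reversed to 0.994 for S2P, and without chromosome 5 it was 1.17 for GATA2. GATA2 overlapped 47.8% of WT and 45.8% of KO RUNX1 peaks among equal numbers of top peaks, 39.9% and 37.4% with reciprocal overlap, and 53.1% in KO at the stricter q. Within 2 kb of gene ends, the KO minus WT difference was 1.55 points for RUNX1 and −0.740 for S2P. The S2P median of genes with RUNX1 in KO alone was 0.818 with summits near gene ends, beside 0.879 for genes bound in both, 0.667 for WT alone and 0.314 for neither.

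Fixed-list genes bound by GATA2 were 9 in WT alone and 13 in KO alone. At the stricter q they were 11 and 16, within 50 kb 4 and 4, and with equal numbers of top peaks 9 and 8, so the excess in KO was absent within 50 kb and turned with equal numbers of top peaks. For RUNX1 they were 3 and 5, at the stricter q 4 and 8, within 50 kb 7 and 1, which turns the direction, and with equal numbers of top peaks 6 and 10. The cause of these turns was not tested.

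Of 1623 further values for single genes, peaks and lists, 1133 stayed (785 equal, 109 higher and 239 lower) and 490 moved (274 higher and 216 lower). The genes with the largest S2P differences kept their direction at the stricter q. They also kept it without 1 kb at both ends, except Pcp2, Egfl8, Ubqln2, Fzd9 and Nradd, which are too short for that. At weak peaks depth limits what a single list can show, since median KO-only summits held 15 (GATA2) and 22 (RUNX1) fragments.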

Other observations

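No test was run on the values below, and the regions were chosen after their values were seen, as windows of 100 kb whose strong peaks lay almost all in 1 genotype.

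Unshared peaks of the factors formed clusters. In KO alone, 9 GATA2 and 5 RUNX1 peaks lay on chromosome 4 between 56300001 and 56400000, outside protein-coding genes, with −log10 q up to 277 for GATA2, and the WT lists had 0 there. GATA2 had 8 and 6 KO-only peaks in adjoining windows of Fgf12, a gene of the fibroblast growth factor family, 6 in Dock10 and 6 at Ncoa1, a nuclear receptor coactivator gene, and RUNX1 had 5 at Dcx and Capn6. Several GATA2 clusters lay on chromosome 5, with 7 KO-only peaks in Ldb2, 5 and 5 in Reln, and 8 between 47300001 and 47400000. In WT alone, GATA2 had 8 peaks in Adarb2, an RNA-editing family gene, and 6 on chromosome 3 between 9600001 and 9700000, and RUNX1 had 5 in Plxnc1, a semaphorin receptor gene.

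S2P also had stretches in 1 genotype. In KO alone, 8 peaks lay on chromosome 3 between 8000001 and 8100000, outside protein-coding genes, with fold enrichment up to 12.3, and 12 lay at Tbc1d21, 8 at Igsf3 and 6 at Cntnap2. In WT alone, 10 lay at the predicted gene Gm5751 on chromosome X. S2P peaks overlapped 28.4% of RUNX1 peaks in WT (27.8 to 28.9) and 30.8% in KO (30.3 to 31.2), and 18.5% and 19.9% of GATA2 peaks, against 6.06% to 6.65% by chance.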
